A study of Mus musculus with 17 samples.

How the data were processed

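The deposited values were whole-number counts per gene symbol in 3 tables, purified TANs, RIL-175 cultures and marrow neutrophils. The submitters' processing notes name Trim Galore, STAR and featureCounts and the build mm10, without versions, so before deposit the authors had trimmed, aligned and counted reads. The totals differed between libraries and the values contradicted no unit. The TAN table held 15596 genes, each with at least 10 counts in at least 2 libraries, so genes with low counts had been removed before deposit by a rule the labels do not state. The RIL-175 table held 54532 entries. The counts of 99 repeated symbols were added up, and 27 entries whose symbols a spreadsheet had turned into dates were kept apart as unnamed genes. That gave 54430 genes, of which 14105 were tested. The marrow table held 25238 genes, and the 5 single-library tables equalled it. Among counts from 1 to 99 even values made up 62.4 to 83.3% in the TAN libraries and 73.8 to 75.1% in the marrow libraries, where single counting gives 50%, against 43.7 to 45% in the RIL-175 libraries. Both mates of a pair were therefore probably counted in the first 2 tables, and the exact intervals for marrow genes (Poisson for a level, binomial for a ratio) use counts divided by 2, a choice made after seeing the data. Of the symbols, 97.8% (TANs), 98.7% (RIL-175) and 96.5% (marrow) were in GENCODE M21 for GRCm38, the source of the positions.

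Counts were filtered with filterByExpr, scaled by TMM and tested in edgeR 4.0.16 by a two-sided quasi-likelihood F test with robust dispersion, in 1 fit per table, so the 3 RIL-175 groups share 1 estimate of the spread. The p-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The biological coefficient of variation was 0.551 in TANs and 0.0475 in RIL-175. Alternatives used DESeq2 1.42.0 with its Wald test, its size factors, a filter of 1 CPM, no filter, a replicate block, only the groups compared, each library left out in turn and a test against a 1.5-fold difference. The comparisons, thresholds, these alternatives, the rule for naming genes and 35 gene lists were fixed before the data were examined. Alternatives added afterwards are called so where they are given. Lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM with a prior of 2 counts and a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Fits ran in R 4.3.3 and figures in Python 3.11.15 with matplotlib 3.10.9.

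Marrow libraries were compared as log2 ratios of CPM with a prior of 2 counts. A gene was measured with at least 50 counts in the higher library and called apart at 2-fold. The median ratio of a list was ranked among 10000 random lists of its size matched on expression in 20 bins. TAN-expressed genes had at least 4 times the CPM in purified TANs that they had in RIL-175 alone, 5131 genes in all. The share of TAN RNA in a coculture was the median, over the 50 genes highest in purified TANs and under 1 CPM in RIL-175 alone, of the coculture level minus the control level divided by the purified level.

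The genes named were chosen by rule. In tested comparisons these were the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap in CPM and whose higher group averaged at least 10 CPM. Eligible in this way were 91 higher and 121 lower genes with SiglecF- TANs, 331 and 428 with SiglecFhi TANs, 86 and 97 between the cocultures and 0 between TANs. Chance gives a non-overlap in 20% of genes for 2 against 3 libraries and in 10% for 3 against 3. For marrow pairs they were the 8 highest and 8 lowest ratios with at least 200 counts in the higher library. For each list described, up to 4 members past the threshold with the smallest adjusted p were added, or in the marrow those with the largest ratios, and a set of genes fixed with the rule was always reported where tested. Alb was not tested in RIL-175. Some genes that the rule names are not reported here. Gene models without a name and ribosomal or mitochondrial copies were counted but not named. In lists of TAN genes, where no gene passed, members are given by value.

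On counts simulated from the means, library sizes and dispersions of these tables, with 200 genes changed, the TAN test recovered 0, 13.4 and 66.7% of genes changed 2, 4 and 16-fold and called 8 unchanged genes of 15318 tested. The RIL-175 tests recovered 32.8, 25.4 and 41.8% at 1.2-fold, 67.2, 65.7 and 74.6% at 1.5-fold and 83.3% each at 2-fold, in the order of the comparisons above, with 8, 12 and 7 unchanged genes called. A simulated list of 25 genes was recovered in all 4 tested comparisons, with 1 other list called in the TAN comparison and 0 in the others. For a pair of marrow libraries, simulated with counting error alone, all 200 genes changed 4-fold were recovered with 2 false calls.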

Results

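Polyadenylated RNA was sequenced in bulk from 17 mouse libraries in 10 groups. Tumour-associated neutrophils (TANs) were sorted by surface SiglecF, a sialic acid-binding lectin best known from eosinophils, into SiglecF- (n = 2) and SiglecFhi (n = 2) cells. RIL-175, a mouse hepatocellular carcinoma line, was cultured alone (n = 2), with SiglecF- TANs (n = 3) or with SiglecFhi TANs (n = 3). Marrow neutrophils were kept in medium alone, with linoleic acid, with GM-CSF, with GM-CSF and linoleic acid, or with both and a small molecule that blocks the pairing of MYC with MAX, called the MYC-MAX inhibitor here. Each marrow condition had 1 library. The SiglecF- TAN libraries held 65325624 and 58566123 counts and the SiglecFhi libraries 70764865 and 60067087. RIL-175 alone held 26700001 and 24891330, the cocultures with SiglecF- TANs 25467708, 29320600 and 31102428, and those with SiglecFhi TANs 26262917, 26586415 and 28319687. The marrow libraries held 48352542 counts in medium, 36337086 with linoleic acid, 44664353 with GM-CSF, 44136671 with both and 52281033 with the inhibitor. Levels are counts scaled to the library total (CPM), as mean ± SD where a group has replicates, and fold changes are log2 ± SE after TMM scaling. The labels do not say whether replicates were separate animals or cultures, so p-values measure the spread between these samples, which may be technical. A count of 3, taken as the limit that a count of 0 allows, was 0.0424 to 0.0512 CPM in a TAN library, 0.0965 to 0.121 CPM in a RIL-175 library and 0.0574 to 0.0826 CPM in a marrow library. This floor was not adjusted for mates of a pair. It is too low in TAN and marrow libraries if both mates were counted there. Intervals and floors cover counting error only. Genes are identified by symbol, and positions are 1-based on GRCm38 (mm10).

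The first comparison asks how SiglecFhi TANs differ from SiglecF- TANs. Siglecf itself, on the plus strand of chromosome 7 at 43351341-43359531, stood at 782 ± 58.8 CPM in the SiglecFhi libraries and 29.3 ± 15.9 CPM in the SiglecF- libraries (n = 2 each), a log2 fold change of 4.21 ± 0.387. It is the sorting marker, so this value checks the labels and is no finding. SiglecFhi TANs had lower values for genes of circulating neutrophils. Ly6g, a neutrophil surface marker (chromosome 15, 75155240-75159126), was at 5.51 ± 5.62 against 131 ± 59.4 CPM, log2 -5.22 ± 1.16. Cxcr2, the receptor that draws neutrophils from marrow to blood, was at 946 ± 17.5 against 1763 ± 52.9 CPM, log2 -1.53 ± 0.389. No gene passed the test: edgeR called 0 of 15596 genes, with 2712 at an unadjusted p under 0.05 and a lowest Benjamini-Hochberg adjusted p of 0.155, which Siglecf had. DESeq2 called 1219 genes, 283 higher and 936 lower in SiglecFhi TANs. A fit with the replicate number as a block called 3278, and leaving out SiglecFhi replicate 1 or 2 gave 4 or 113. Without SiglecFhi replicate 2, Siglecf (adjusted p 0.000197) and Ly6g (0.00117) passed. Each such fit leaves 1 library in a population, which is assumed to vary like the 2 libraries of the other. Library-total scaling moved the median log2 fold change of all genes from 0.0532 to 0.617, so CPM ratios run higher than the fitted fold changes. The direction of the genes and lists named for this comparison is the one under TMM, with the exceptions named beside them.

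The 25 literature markers of SiglecFhi TANs had a median log2 fold change of 0.326 and a mean of 0.627, with 17 positive values. Adjusted over the list alone, 5 were higher and 2 lower, and camera gave an adjusted p of 0.148 (0.0334 without SiglecF- replicate 1). Ltc4s, leukotriene C4 synthase (chromosome 11, 50236461-50238616), was at 157 ± 31.5 against 4.54 ± 4.15 CPM, log2 4.64 ± 0.671. Pald1 was at 122 ± 8.8 against 9.2 ± 7.42 CPM, log2 3.25 ± 0.523. Cd14, the lipopolysaccharide co-receptor, and Cxcl3, a neutrophil chemokine, had log2 fold changes of -2.40 ± 0.382 and -2.37 ± 0.263. Vegfa, the angiogenic growth factor (chromosome 17, 46016993-46032369), was at 642 ± 85.2 against 217 ± 29.8 CPM, log2 0.91 ± 0.368 (edgeR adjusted p 0.304), with 0.52 within libraries numbered 1 and 1.41 within those numbered 2. Cd274, which encodes PD-L1 (chromosome 19, 29367455-29388095), was at 134 ± 1.47 against 70.5 ± 23.2 CPM, log2 0.36 ± 0.217 (adjusted p 0.477). Ccl3 was at 943 ± 547 against 279 ± 182 CPM, log2 1.06 ± 0.814 (adjusted p 0.596), and Tnf had log2 0.56 ± 0.618 (adjusted p 0.752). Arg1 and Spp1, for arginase and osteopontin, had log2 fold changes of -0.48 ± 1 and -0.45 ± 1.1, which became 0.02 and 0.04 under library-total scaling. Tgfb1 had 0.32 ± 0.424 and Hif1a -0.82 ± 0.259 (160 against 184 CPM), and their adjusted p were 0.81 and 0.231. Xbp1 had 0.08 ± 0.245, which DESeq2 scaling turned to -0.11, and Csf2rb -0.19 ± 0.33, Cd36 -0.05 ± 0.858 and Hilpda -0.51 ± 0.663 turned positive under library-total scaling. Plin2, a lipid droplet coat protein, had -0.79 ± 0.336 (adjusted p 0.325) and Fabp5, a fatty acid chaperone, -1.15 ± 0.557 (adjusted p 0.379).

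Of 35 lists tested, limma camera with its preset correlation of 0.01 placed 13 apart from the other genes, 1 higher and 12 lower in SiglecFhi TANs. None held with an estimated correlation, where the lowest adjusted p was 0.514, and fry called 0. No member of any list passed over all genes, so the counts that follow are those adjusted over the list alone. The 25 circulating neutrophil genes were lower, with a median of -3.19, 25 negative values, 22 lower members (adjusted p 2.26e-19 with the preset correlation, 0.522 with an estimated correlation) and medians of -3.42 and -2.75 within numbers 1 and 2. Il1r2 was the only one to turn positive under library-total scaling. Retnlg, a resistin-like granulocyte protein (chromosome 16, 48872621-48874496), was at 215 ± 184 against 5136 ± 1750 CPM, log2 -5.21 ± 1.04. S100a8 and S100a9, the calprotectin subunits, had log2 fold changes of -3.24 and -3.10. The 18 pan-neutrophil genes had a median of -1.85 with 12 lower members (adjusted p 2.04e-11, and 0.514 with an estimated correlation). The 20 granule genes of the marrow had -1.81 with 10 lower (1.68e-08, and 0.514 with an estimated correlation). Camp, the cathelicidin, was at 7.05 against 207 CPM and Ngp, another granule protein, at 65.4 against 1664 CPM. The 18 pan-leukocyte genes had -1.02 with 0 lower (6.84e-08, and 0.63 with an estimated correlation).

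The list higher in SiglecFhi TANs held 37 MYC targets of ribosome biogenesis and nucleotide supply. Their median was 1.02, with 5 higher members and 35 positive values under TMM (adjusted p 1.39e-06, and 0.63 with an estimated correlation), and it was 1.37 and 0.603 within numbers 1 and 2. DESeq2 scaling turned Odc1, Shmt2 and Slc19a1 negative. Ppan and Nop58, which act in ribosome assembly, had log2 fold changes of 1.87 ± 0.361 and 1.75 ± 0.452. Myc itself (chromosome 15, 61985391-61990374) was at 18.6 ± 0.737 against 11.2 ± 5.18 CPM, log2 0.19 ± 0.337 (edgeR adjusted p 0.88), with 0.57 and -0.15 within the numbers. The 19 glycolysis genes had a median of -1.09 with 6 lower members (adjusted p 2.13e-08, and 0.615 with an estimated correlation). Slc16a3, a lactate exporter, was at 312 ± 39.2 against 1259 ± 264 CPM, log2 -2.61 ± 0.329, and Slc2a3, a glucose transporter, had -2.60 ± 0.764. Hk1, Aldoc, Tpi1 and Pgam1 turned positive under library-total scaling. The 37 interferon response genes had a median of -0.63 with 12 lower (4.85e-06, and 0.514 with an estimated correlation), among them Oas3, an antiviral synthetase, at 30.9 against 158 CPM. The 20 NRF2 targets had -0.90 with 0 lower (0.00014, and 0.514), and the 32 NF-kB and TNF response genes -0.60 with 0 lower (0.00279, and 0.514, both second values with an estimated correlation). Smaller falls were called for hypoxia (24 genes, -0.48, adjusted p 0.011, and 0.0791 without SiglecFhi replicate 1), fatty acid metabolism (34 genes, -0.30, 0.0216, and 0.248 without SiglecFhi replicate 1 or 0.299 without SiglecF- replicate 2) and immunosuppressive mediators (23 genes, -0.46, 0.0275, and 0.0763 without SiglecF- replicate 2). Epithelial and matrix genes (23, -0.41) had 0.0247, which became 0.116 without SiglecFhi replicate 1 and 0.247 without SiglecF- replicate 2. The medians of these last 4 lists turned positive under library-total scaling, while relative to the median of all genes they stayed negative, and with an estimated correlation their adjusted p were 0.514, 0.802, 0.514 and 0.514.

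Other cell types were measured beside these groups. Hepatocyte genes differed between numbers more than between the sorted populations: Alb was at 4903 ± 5130 CPM in SiglecFhi and 4670 ± 4540 CPM in SiglecF- libraries (n = 2 each), and the list had a median of -0.45, which library-total scaling turned to 0.0507, as it turned Alb from -0.43 to 0.07 (camera adjusted p 0.151, 5.75e-06 without SiglecFhi replicate 2 and 0.00828 without SiglecF- replicate 1). Macrophage genes had a median of 1.93 within number 1 and -0.39 within number 2, MHC class II genes 1.67 and -0.13, and eosinophil genes 1.46 and -0.29. Their pooled medians were 0.673, 1.08 and 0.47, and none was called (adjusted p 0.569, 0.161 and 0.762), though without SiglecFhi replicate 2 the first had 0.0139 and the second 5.71e-05, with the lone SiglecFhi library assumed to vary like the SiglecF- libraries.

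**Figure D1:**
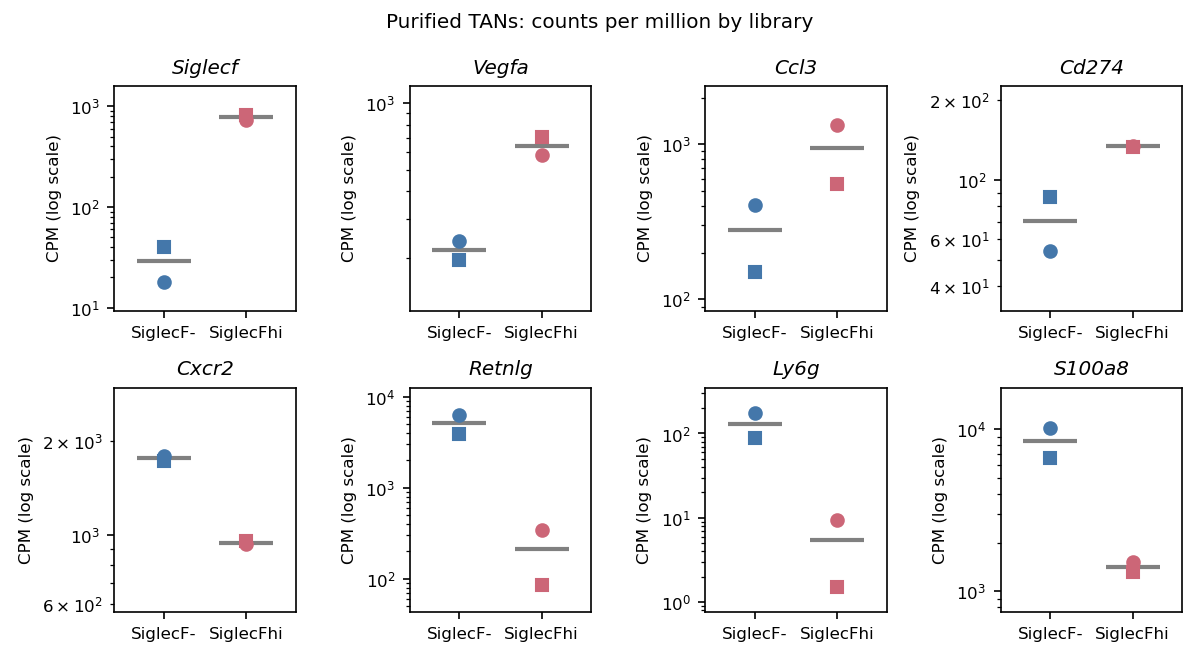
CPM (log axis) of named genes in the 4 purified TAN libraries, with circles for libraries numbered 1, squares for those numbered 2 and gray bars for group means. Retnlg averaged 215 CPM in SiglecFhi and 5136 CPM in SiglecF- TANs, and Ccl3 943 ± 547 and 279 ± 182 CPM.

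The next comparison asks what coculture with SiglecF- TANs does to RIL-175. Cxcl5, Cxcl1 and Nfkbia rose, and Lgals4 fell. Cxcl5, a CXCR2 ligand that draws neutrophils (chromosome 5, 90759360-90761624), was at 24.5 ± 1.67 CPM with SiglecF- TANs (n = 3) and 13.4 ± 1.09 CPM alone (n = 2), log2 0.86 ± 0.0844 (edgeR adjusted p 3.57e-09). Cxcl1, another CXCR2 ligand (chromosome 5, 90891241-90893115), was at 9.22 ± 0.742 against 4.81 ± 0.869 CPM, log2 0.93 ± 0.149 (0.000116). Nfkbia, the NF-kB inhibitor that NF-kB itself induces (chromosome 12, 55489410-55492647), was at 41.1 ± 0.593 against 24.7 ± 3.17 CPM, log2 0.72 ± 0.0735 (3.78e-08). Lgals4, an epithelial galectin (chromosome 7, 28833854-28841708), fell from 141 ± 8.14 to 98.8 ± 4.51 CPM, log2 -0.53 ± 0.0451 (4.54e-10). In all, edgeR called 269 genes higher and 170 lower of 14105, with 2050 at an unadjusted p under 0.05, and without SiglecF- coculture replicate 1 the total of 439 fell to 283. Of the genes called higher, 179 were at least 4-fold above RIL-175 alone in purified TANs, called TAN-expressed here, and 93 had no count in RIL-175 alone. Of the genes called lower, 164 were not TAN-expressed. Among genes at 1 CPM or more in RIL-175 alone the median size was log2 0.291 for those higher and 0.177 for those lower, and 6 and 1 reached 2-fold. Cxcl1 (75.7 CPM in purified TANs) and Nfkbia (3923 CPM) are TAN-expressed, and Cxcl5 and Lgals4 are not. Testing without TAN-expressed genes left 73 higher and 104 lower.

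Named by rule, Tnfrsf1b, a TNF receptor, rose from 11.3 to 19.5 CPM (log2 0.78 ± 0.0966, adjusted p 4.17e-07), Gdpd5 from 14.1 to 23.7 CPM (0.74 ± 0.0857), Ikbke, a kinase of innate signalling, from 13.8 to 21.6 CPM (0.64) and Zc3h12a, an RNase that limits inflammatory transcripts, from 9.27 to 13.4 CPM (0.52). Neurl3 had 0.57. Cxcl2 was at 17.0 against 0.170 CPM and Mpeg1, a macrophage and neutrophil perforin-like gene, at 11.1 against 0.0977 CPM, and without RIL-175 alone replicate 1 the adjusted p of Mpeg1 was 0.0678. Ap5z1 had 0.54, and its adjusted p of 0.0117 became 0.0732, 0.0769 and 0.342 without SiglecF- replicate 1, SiglecF- replicate 3 and RIL-175 alone replicate 1. Among genes that fell, Hist1h2bc had log2 -0.60, Pla2g7, a secreted phospholipase, -0.51, Gsta1, a glutathione transferase, -0.46, and Aqp8, a water channel (chromosome 7, 123462291-123468004), -0.45, from 44.7 ± 3.97 to 32.9 ± 2.78 CPM (5.60e-05). Krt79, a keratin, fell from 42.9 to 33.1 CPM (-0.39, adjusted p 0.00022) and Serf2 from 64.7 to 51.0 CPM (-0.36). Without RIL-175 alone replicate 2 the adjusted p of Hist1h2bc was 0.0509. Cd274 rose from 1.48 ± 0.338 to 5.70 ± 1.45 CPM (log2 1.92 ± 0.272, adjusted p 0.000267), and it is TAN-expressed, at 102 CPM in purified TANs. So are Tnfrsf1b, Neurl3, Zc3h12a, Cxcl2, Mpeg1 and Pla2g7 (550, 1211, 275, 9038, 658 and 661 CPM), while Gdpd5, Ikbke, Ap5z1, Aqp8 and Krt79 are not. H2-K1 was at 70.3 ± 2.67 against 63.0 ± 0.685 CPM (adjusted p 0.11), B2m at 119 against 109 CPM (0.141) and Myc at 200 against 189 CPM (0.301). H2-D1 rose from 118 ± 4.59 to 131 ± 4.32 CPM (log2 0.14 ± 0.0397, adjusted p 0.0347) and Irf1 from 20.8 to 25.5 CPM (0.28 ± 0.0765, 0.0323), and H2-K1, B2m, H2-D1 and Irf1 are TAN-expressed. The call of H2-D1 ended without RIL-175 alone replicate 2 (0.217), SiglecF- replicate 1 or 2 (0.111, 0.21) or SiglecFhi replicate 2 (0.0533) and with DESeq2 (0.101). That of Irf1 ended without RIL-175 alone replicate 1 or 2 (0.12, 0.0776) or any SiglecF- replicate (0.0576, 0.157 and 0.068) and with DESeq2 (0.0991). Afp, Ifngr1, Tnfrsf1a, Cflar, Casp8 and Ptgs2 had adjusted p of 0.932, 0.977, 0.931, 0.509, 0.588 and 0.836.

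Lists of leukocyte genes were among those called. Of 26 lists tested, camera called 8 higher and 2 lower, and 5 held with an estimated correlation. Of 33 NF-kB and TNF response genes, 22 rose, 0 fell and 11 did not pass, and adjusted over the list alone 29 rose (median log2 0.44, adjusted p 3.35e-28, and 0.0363 with an estimated correlation). Of 15 pan-neutrophil genes, 14 rose and 1 did not pass, or 15 adjusted over the list alone. Their fitted median of 7.91 includes 10 genes with no count in RIL-175 alone, and with those at their bound it was 5.46 (2.01e-33, and 0.0363 with an estimated correlation). Of 18 pan-leukocyte genes, 15 rose (17 adjusted over the list alone), with a median of 3.95 at the bound (1.67e-28, 0.0363). Of 19 circulating neutrophil genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 3.28 at the bound (5.08e-19, 0.0363). For genes absent from RIL-175 alone, the rise was at least 162-fold for Ccl3, a neutrophil and macrophage chemokine (9.42 CPM), at least 164-fold for Lcn2 (9.55 CPM), at least 54.1-fold for Csf3r (3.14 CPM) and at least 38.5-fold for S100a9 (2.24 CPM), against a floor of 0.0581 CPM over the control group. S100a8 rose from 0.0763 to 4.26 CPM, Srgn was at 2.87 against 0.0388 CPM and Lcp1 at 4.29 against 0.0562 CPM.

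The 7 granule genes tested included 4 that rose and 1 that fell, or 5 and 1 adjusted over the list alone (median 2.52 at the bound, camera adjusted p 2.98e-05, and 0.118 with an estimated correlation). Of 23 SiglecFhi TAN markers, 9 rose and 1 fell, or 10 and 1 over the list alone (median 0.131, adjusted p 3.51e-07, 0.118 with an estimated correlation, and 0.286 in the other direction without TAN-expressed genes). Of 17 GM-CSF and STAT5 response genes, 6 rose, or 7 with 1 lower over the list alone (0.178, 3.51e-07, 0.0451 with an estimated correlation, and 0.583 in the other direction without TAN-expressed genes). Of 6 macrophage genes, 2 rose, the same number over the list alone (0.227 at the bound, 0.000597, 0.181 with an estimated correlation). The 26 oxidative phosphorylation genes and the 30 fatty acid genes had medians of -0.05 and -0.06 with no member past the test, also adjusted over the list alone (adjusted p 0.000341 and 0.00435, and 0.118 for both with an estimated correlation). The 15 MHC class I genes had 3 higher members (5 adjusted over the list alone, camera adjusted p 0.145, 0.0496 without SiglecF- replicate 1). Among them the TAN-expressed Tapbp (328 CPM in purified TANs), the tapasin that loads peptide onto MHC class I (chromosome 17, 33915899-33929292), was at 38.2 ± 2.54 against 31.2 ± 2.04 CPM (log2 0.28, adjusted p 0.00797, and 0.0812 without SiglecF- replicate 2 and 0.155 without RIL-175 alone replicate 1).

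In coculture with SiglecFhi TANs, Cxcl5, Cxcl1, Vcam1 and H2-K1 rose, and Lgals4 and Vil1 fell. Cxcl5 was at 57.5 ± 4.57 CPM (n = 3), log2 2.09 ± 0.0812 over RIL-175 alone (n = 2, edgeR adjusted p 4.54e-20), and Cxcl1 at 17.9 ± 2.93 CPM, log2 1.89 ± 0.144 (3.98e-11). Vcam1, an adhesion molecule for leukocytes (chromosome 3, 116109949-116129688), rose from 25.1 ± 3.14 to 53.7 ± 1.28 CPM, log2 1.09 ± 0.0711 (1.19e-13). H2-K1, a classical MHC class I heavy chain (chromosome 17, 33996017-34000347), rose from 63.0 ± 0.685 to 80.6 ± 1.97 CPM, log2 0.34 ± 0.0479 (1.61e-06). Lgals4 fell to 73.0 ± 3.73 CPM, log2 -0.96 ± 0.0457 (1.85e-16), and Vil1, the villin of microvilli, fell from 91.2 ± 1.35 to 57.2 ± 5.35 CPM, log2 -0.68 ± 0.0532 (1.89e-11). In all, edgeR called 587 genes higher and 515 lower, with 2617 at an unadjusted p under 0.05. Of those higher, 275 were TAN-expressed and 114 had no count in RIL-175 alone, and of those lower, 491 were not TAN-expressed. Among genes at 1 CPM or more in RIL-175 alone the median size was 0.273 for those higher and 0.228 for those lower, and 25 and 17 reached 2-fold. Of the genes named first, Cxcl1 and H2-K1 (1070 CPM in purified TANs) are TAN-expressed, and Cxcl5, Vcam1, Lgals4 and Vil1 are not. Without TAN-expressed genes the test called 324 higher and 398 lower.

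Ccl2, a monocyte chemokine, rose from 2.56 to 12.0 CPM (log2 2.22 ± 0.161, adjusted p 3.14e-13), Cxcl3 from 0.590 to 11.8 CPM (4.32 ± 0.246), Clca3b from 5.87 to 21.8 CPM (1.88 ± 0.113, 4.39e-15), Nfkbia to 57.6 ± 4.5 CPM (1.21 ± 0.0726, 2.22e-13) and Stab1, a scavenger receptor, from 4.15 to 11.8 CPM (adjusted p 0.00487). Mpeg1 was at 10.1 CPM, and without RIL-175 alone replicate 1 its adjusted p was 0.0503. Il1b was at 10.2 against 0.0187 CPM, Cxcl2 at 21.1 against 0.170 CPM, and Acod1, which makes itaconate, rose at least 104-fold to 6.04 CPM. Aqp8 fell to 23.2 ± 1.35 CPM (-0.96 ± 0.0742, 6.27e-12), Krt79 to 24.2 CPM (-0.84, 1.64e-11), Hsd17b14, a steroid dehydrogenase, from 11.0 to 6.03 CPM (-0.88) and Itgb4, an integrin of hemidesmosomes, from 12.7 to 7.68 CPM (-0.73). Hist1h2bc, Thsd4, Pla2g7 and Iqgap2 had log2 fold changes of -0.95, -0.71, -0.64 and -0.63. Cd274 was at 6.74 ± 1.61 CPM (2.17 ± 0.269, adjusted p 2.79e-05). Ccl2, Cxcl3, Nfkbia, Stab1, Mpeg1, Il1b, Cxcl2, Acod1, Pla2g7 and Cd274 are TAN-expressed. Myc was at 207 against 189 CPM (0.12 ± 0.033, adjusted p 0.0141, but 0.141 without RIL-175 alone replicate 1 and 0.0712 without SiglecFhi replicate 3). Csf2, which encodes GM-CSF, was at 6.57 against 4.46 CPM (0.55 ± 0.167, adjusted p 0.0341), and its call ended without RIL-175 alone replicate 1 or 2 (0.167, 0.0619) or SiglecFhi replicate 2 or 3 (0.0974, 0.121). Ifngr1, Tnfrsf1a, Cflar, Casp8, Ptgs2 and Afp had adjusted p of 0.368, 0.766, 0.196, 0.06, 0.446 and 0.855.

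Of the 26 lists, camera called 11 higher and 2 lower, and 4 held with an estimated correlation. Of 33 NF-kB and TNF response genes, 29 rose and 4 did not pass, or 31 rose adjusted over the list alone (median 0.829, adjusted p 1.18e-34, and 0.0478 with an estimated correlation). Its 11 members that are not TAN-expressed, among them Relb, Nfkb1, Traf1 and Cxcl5, had a median of 0.777 (3.18e-13), against 0.389 (8.76e-08) with SiglecF- TANs. Of 15 MHC class I genes, 6 rose, or 8 adjusted over the list alone, and 9 did not pass (0.159, adjusted p 8.75e-05, and 0.0524 with an estimated correlation). Its 8 members that are not TAN-expressed had a median of 0.0805 and none called, and the list was not called on them (0.338). Tapbp rose to 50.8 ± 1.66 CPM (0.70 ± 0.0649, 2.42e-10), B2m, the light chain, from 109 to 138 CPM (0.34 ± 0.0396, 4.26e-08), H2-D1 from 118 ± 4.59 to 148 ± 5.53 CPM (0.32, 1.53e-07) and Irf1 from 20.8 to 29.6 CPM (0.49 ± 0.0762, 1.05e-05), and these 4 are TAN-expressed, at 328, 876, 2272 and 543 CPM in purified TANs. Of 19 interferon response genes, 3 rose, or 4 adjusted over the list alone (0.434, 0.00812, 0.114 with an estimated correlation, 0.758 without TAN-expressed genes, and 0.0651 without RIL-175 alone replicate 1). These were Ddx58, Irf9 and Ifi35, with log2 fold changes of 0.71, 0.48 and 0.43, whose adjusted p without that library were 0.145, 0.124 and 0.457, and the first 2 are TAN-expressed. Irf9 also had 0.0574 without RIL-175 alone replicate 2 and 0.247 without SiglecFhi replicate 3, and Ifi35 had 0.0612, 0.0637 and 0.127 without SiglecFhi replicates 1, 2 and 3. Of 17 GM-CSF and STAT5 response genes, 10 rose and 2 fell, also adjusted over the list alone (0.286, 2.77e-06, 0.0524 with an estimated correlation, and 0.383 in the other direction without TAN-expressed genes). Of 17 immunosuppressive mediators, 6 rose and 3 fell, or 7 and 3 over the list alone (0.212, 0.008, 0.315 with an estimated correlation, 0.383 in the other direction without TAN-expressed genes and 0.0798 without RIL-175 alone replicate 1).

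Of 30 fatty acid genes, 1 rose and 5 fell, or 1 and 8 adjusted over the list alone (median -0.08, camera adjusted p 0.000549, and 0.061 with an estimated correlation). Pparg, a lipid-sensing nuclear receptor, fell from 89.7 to 70.7 CPM (-0.35 ± 0.0485, 1.24e-06), and Dgat2, which makes triglyceride, from 72.3 to 58.6 CPM (-0.31, 3.40e-05). Of 7 hepatocyte genes, 2 fell, or 3 adjusted over the list alone (-0.20, adjusted p 0.0333, and 0.131 with an estimated correlation). Those were Krt8 and Krt18, keratins of simple epithelia, with log2 fold changes of -0.21 each, and the call of the list ended without SiglecF- replicate 2, RIL-175 alone replicate 1 or SiglecFhi replicate 2 (0.0518, 0.166 and 0.189). Of 22 epithelial and matrix genes, 5 rose and 5 fell, and the list was not called (adjusted p 0.699). Itga5, a fibronectin receptor subunit, rose from 98.7 to 135 CPM (0.44), and Cdh1, E-cadherin, fell from 184 to 156 CPM (-0.25). Bcl2l11, a TAN-expressed, death-promoting BCL2 relative, rose from 22.2 to 36.4 CPM (0.70, 1.89e-09) and Hk2, a hexokinase, from 120 to 149 CPM (0.30, 2.28e-06). Of 37 MYC targets, 2 rose, also adjusted over the list alone, and the list was not called (0.168, but 0.0186 without RIL-175 alone replicate 2 and 0.0391 without SiglecFhi replicate 1).

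Leukocyte genes rose here too. Of 15 pan-neutrophil genes, 14 rose, or 15 adjusted over the list alone (median 4.5 at the bound, adjusted p 6.05e-26, and 0.0478 with an estimated correlation), and of 18 pan-leukocyte genes, 17 rose by either count (4.25 at the bound, 3.20e-25, 0.0478). Of 19 circulating neutrophil genes, 12 rose and 2 fell, or 15 and 2 over the list alone (3.54 at the bound, 4.33e-12, 0.0478). Of 6 macrophage genes, 4 rose, or 6 over the list alone (1.99 at the bound, 1.34e-06, and 0.0803 with an estimated correlation). Of 7 granule genes, 4 rose and 1 fell by either count (3.15 at the bound, 3.28e-05, 0.0901), and of 23 SiglecFhi TAN markers, 10 rose, or 11 with 1 lower over the list alone (0.114, 6.08e-08, 0.0901 and, without TAN-expressed genes, 0.828 in the other direction). The rise was at least 217-fold for Ccl3 (12.6 CPM), 98.7-fold for Lcn2 (5.74 CPM), 69.7-fold for Tnf (4.05 CPM), 54.6-fold for Adgre1, a macrophage marker (3.17 CPM), 28.9-fold for Csf3r (1.68 CPM) and 11.7-fold for S100a9 (0.678 CPM). S100a8 rose to 1.44 CPM and Ptprc, the leukocyte common antigen, from 0.0763 to 1.52 CPM.

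**Figure D2:**
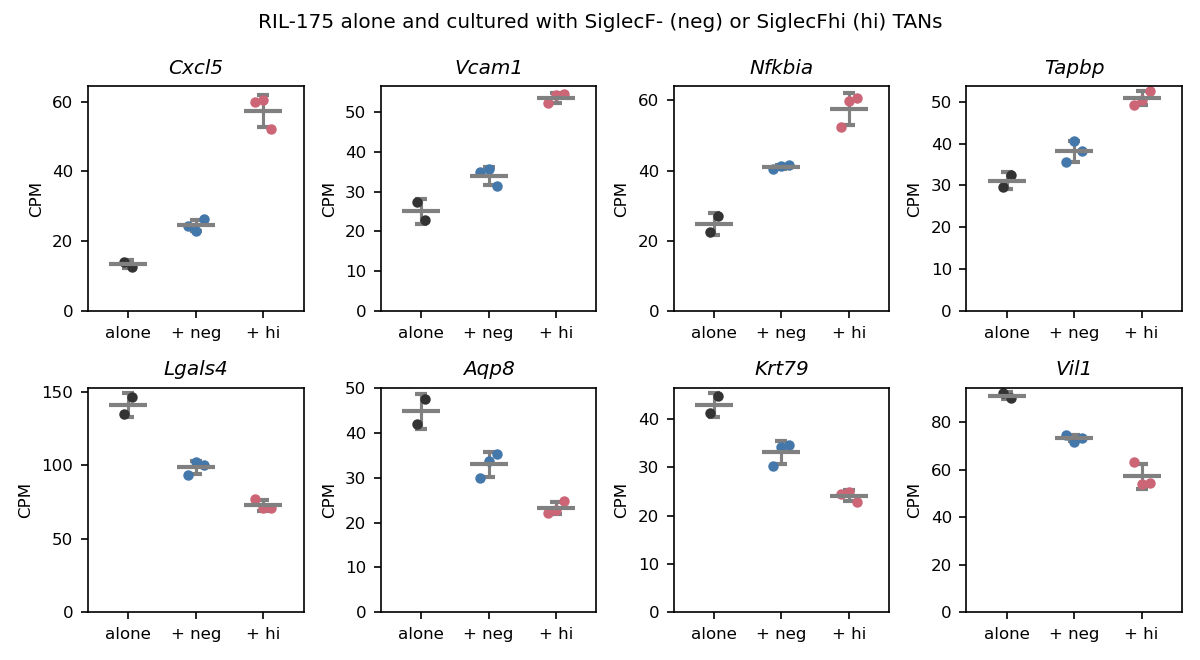
CPM (axes from 0) of named genes in RIL-175 alone (2 libraries), with SiglecF- TANs (3) and with SiglecFhi TANs (3), with points for libraries and bars for the mean ± SD. Cxcl5 averaged 13.4, 24.5 and 57.5 CPM in that order, and Lgals4 141, 98.8 and 73.0 CPM.

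The direct test of the cocultures against each other asks whether SiglecFhi TANs act differently from SiglecF- TANs on RIL-175. Cxcl5, Cxcl1, Vcam1 and Tapbp were higher with SiglecFhi TANs, and Lgals4 and Aqp8 were lower. Cxcl5 differed by log2 1.23 ± 0.0644 (n = 3 each, edgeR adjusted p 1.22e-15), Cxcl1 by 0.96 ± 0.113 (3.17e-06), Vcam1 by 0.66 ± 0.0599 (3.34e-09) and Tapbp by 0.42 ± 0.0557 (5.51e-06). Lgals4 differed by -0.43 ± 0.0421 (3.42e-08) and Aqp8 by -0.50 (1.09e-05). In all, 134 genes were higher and 118 lower, with 1525 at an unadjusted p under 0.05, and 61 of those higher, Cxcl1 and Tapbp among them, were TAN-expressed while 107 of those lower were not. The total of 252 depended on single libraries. It was 439 and 434 without RIL-175 alone replicate 1 or 2, 164 and 135 without SiglecF- replicate 1 or 2, and 145 and 131 without SiglecFhi replicate 2 or 3. A test against a 1.5-fold difference called 22.

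By rule, Cxcl3, Clca3b, Ccl2 and Gdpd5 were higher by log2 1.19 ± 0.144, 1.17 ± 0.0912, 1.05 ± 0.122 and 0.64 ± 0.0687, and Nfkbia by 0.49 ± 0.0598. Mycl, a MYC relative, rose from 14.2 to 20.1 CPM (0.51 ± 0.0823, 0.00012), and Rab32 from 9.27 to 13.1 CPM (0.50, 0.00935, but 0.113 without SiglecF- replicate 3 and 0.183 without SiglecFhi replicate 2). Krt79 had -0.45 (1.57e-05), Myo7b, a brush border myosin, -0.41, from 37.5 to 28.1 CPM, and Iqgap2 -0.36 (4.24e-06). H2-K1 was higher by 0.20 ± 0.042 (0.00384, but 0.0712 without SiglecF- replicate 2 and 0.0511 without SiglecFhi replicate 3), H2-D1 by 0.18 (0.002, 0.0588 without SiglecFhi replicate 3) and B2m by 0.23 (4.48e-05). Csf1, the macrophage growth factor, rose from 68 to 86.5 CPM (0.35 ± 0.045, 3.17e-06). Cd274, Irf1 and Myc had adjusted p of 0.732, 0.0904 and 0.569, and Irf1 passed without RIL-175 alone replicate 1 or 2 (0.0481, 0.0419). Cxcl3, Ccl2, Nfkbia, Rab32, H2-K1, H2-D1, B2m and Csf1 are TAN-expressed. Of 26 lists, camera called 7 higher and 1 lower, and none held with an estimated correlation. Of 33 NF-kB and TNF response genes, 17 were higher and 1 lower, or 24 and 2 adjusted over the list alone (median 0.334, adjusted p 6.27e-19, and 0.136 with an estimated correlation), and the 11 members that are not TAN-expressed had 0.336 (2.00e-11). Of 15 MHC class I genes, 4 were higher, or 7 over the list alone, and 15 had positive values (0.146, 8.73e-07, and 0.0946 with an estimated correlation). Its 8 members that are not TAN-expressed had 0.0852 with none called (0.0443).

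Genes of leukocytes did not move together between the cocultures. Of 6 macrophage genes, 2 were higher, or 4 adjusted over the list alone (0.457, camera adjusted p 0.000155, and 0.292 with an estimated correlation), and Adgre1 had 1.84 ± 0.293 (0.000121). Cybb, the NADPH oxidase subunit, rose from 0.608 to 4.23 CPM (2.80 ± 0.274, 1.40e-08), and Saa3, an acute phase protein, from 0.273 to 3.0 CPM (3.42 ± 0.392, 1.54e-06). Of 19 circulating neutrophil genes, 2 were higher and 4 lower, or 2 and 9 over the list alone (-0.56, 0.00437, and 0.388 with an estimated correlation). S100a8 was lower by -1.56 ± 0.227 (1.86e-05). S100a9 had -1.72 ± 0.367 (0.00756), which became 0.277 without SiglecF- replicate 3 and 0.0709, 0.0546 and 0.119 without SiglecFhi replicates 1, 2 and 3. The 15 pan-neutrophil genes had 1 higher and 3 lower member, or 3 and 5 over the list alone, a median of 0.0124, a mean of -0.25 and a downward test (adjusted p 0.772). Of 23 SiglecFhi TAN markers, 5 were higher, or 5 and 1 lower over the list alone (0.0425, 0.00382, 0.416 with an estimated correlation, 0.185 without TAN-expressed genes, and 0.136 without SiglecF- replicate 1). No member of the interferon list (0.291, 0.00847, 0.292 with an estimated correlation, 0.669 without TAN-expressed genes, 0.0601 without SiglecFhi replicate 3) or the oxidative phosphorylation list (0.03, 0.0421, 0.416) passed by either count. The latter had 0.218 without SiglecF- replicate 1 and 0.147 and 0.118 without SiglecFhi replicates 1 and 2. Of 21 TGF-beta response genes, 1 was higher, or 2 over the list alone (0.0444, 0.0319, 0.416 with an estimated correlation, 0.185 without TAN-expressed genes), and the adjusted p was 0.0713, 0.165 and 0.236 without SiglecF- replicate 1 or 2 or SiglecFhi replicate 3.

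Both coculture comparisons share the 2 libraries of RIL-175 alone, which cannot be split. They had 222 higher and 114 lower genes in common and 0 in opposite directions, where independent lists would share 11.2 and 6.21. In simulations that drew every RIL-175 library, controls included, around the control means, the unchanged groups shared at most 3 in either direction. The simulations used a spread common to all groups. The chi-square of counts between replicates, over its degrees of freedom, was 7.9 for the control pair and 3.33 to 4.37 for coculture pairs. Sharing through the controls may therefore be underestimated by the simulations. The log2 fold changes correlated across genes at 0.926, against 0.615 on average in the simulations, and genes are not independent replicates. Without TAN-expressed genes 121 were in common. Over those 12401 genes the correlation was 0.66, inside the range of the simulations, whose highest was 0.683, and the covariance 0.0573, above their highest of 0.0386. Over the 11500 genes expressed in RIL-175 alone, a restriction chosen after seeing the data, both were above the simulations, the correlation at 0.737 (highest 0.685) and the covariance at 0.024 (highest 0.0143). Counts of pan-neutrophil genes took 0.000214 ± 3.25e-05% of RIL-175 alone, 0.00452 ± 0.000933% with SiglecF- TANs and 0.00453 ± 0.000789% with SiglecFhi TANs, and 6.65 ± 0.694% and 3.16 ± 0.511% of purified SiglecF- and SiglecFhi TANs. From 50 genes abundant in purified TANs, the median share of TAN RNA was 0.0631 ± 0.017% with SiglecF- and 0.0798 ± 0.0167% with SiglecFhi TANs (n = 3 each). Genes differed: with SiglecFhi TANs S100a9 stood at 0.0246% of its purified level, S100a8 at 0.102%, Cybb at 2.95% and Saa3 at 20.9%. The last 4 were named after their values were seen.

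**Figure D3:**
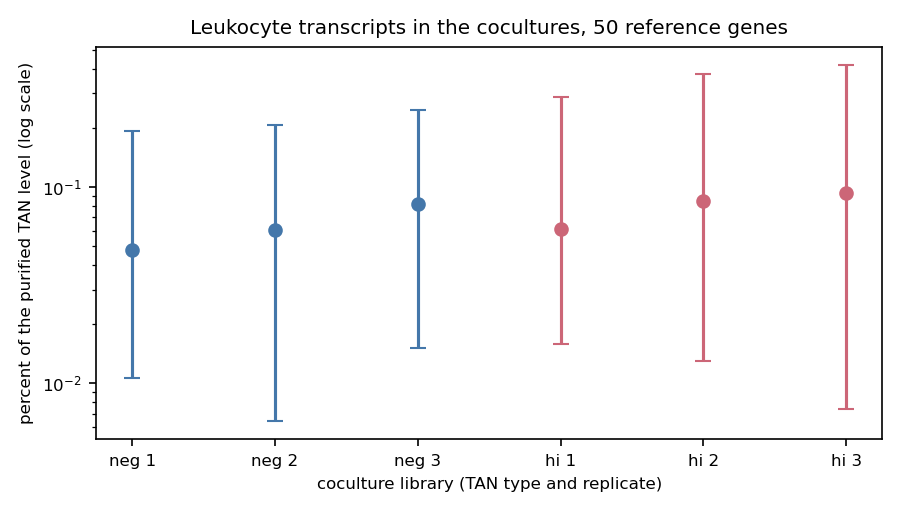
Share of TAN RNA in percent (log axis) in each of the 6 coculture libraries, as the median over 50 reference genes with bars from the 10th to the 90th percentile. The group means of the medians are 0.0631% and 0.0798%, and the 90th percentile is 16.3 to 56.7 times the 10th.

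The marrow libraries ask what GM-CSF, linoleic acid and the MYC-MAX inhibitor do to neutrophils in culture. With 1 library per condition there is no replicate check and no p-value, so ratios are given with exact binomial 95% intervals of their counts, and lists with the percentile of their median among 10000 random lists matched on expression. With GM-CSF, 19 of 25 markers of SiglecFhi TANs were at least 2-fold higher than in medium. Siglecf was at 78.6 CPM with GM-CSF and 8.07 CPM in medium, log2 3.28 (3.07 to 3.51). Cd274 was at 409 against 12.7 CPM, log2 5.01 (4.85 to 5.18), and Spp1 (chromosome 5, 104435118-104441050) at 335 against 16.2 CPM, log2 4.37 (4.22 to 4.52). Ccl3 (chromosome 11, 83647844-83649355) had log2 3.59 (3.53 to 3.66), Xbp1 3.90, Tnf 3.16, Csf2rb, the GM-CSF receptor subunit, 2.72, Tgfb1 2.18 and Hif1a 2.13. Myc was at 9.78 against 2.73 CPM, log2 1.83 (1.43 to 2.26), Vegfa at 53.4 against 56.5 CPM, and Ly6g at 55.9 against 269 CPM, log2 -2.26 (-2.35 to -2.18). Cxcr2 had -0.67 and Plin2 -0.36. In all, 1733 genes were at least 2-fold higher and 1383 lower of 11110 measured. Of 25 SiglecFhi TAN markers, 19 were 2-fold higher and 0 lower (median 3.16, percentile 100), with Clec4n at 7.44 and Csf1 at 7.12. Of 22 GM-CSF and STAT5 response genes, 19 were higher (3.75, 100), of 27 NF-kB genes, 24 (2.57, 100), and of 37 MYC targets, 29 (1.43, 100), with Gnl3, a nucleolar GTPase, at 3.29. Of 24 cholesterol synthesis genes, 18 were higher and 1 lower (1.47, 100), and of 11 MHC class II genes, 8 were higher (1.18, 99.88). Of 7 dendritic genes, 4 were higher and 1 lower (2.27, 99.84, but a median of -0.0577 at 20 counts), and of 10 erythroid genes, 9 were lower (-1.30, 0.02). Of 16 macrophage genes, 3 were higher and 10 lower (-1.26, 0), with Apoe at -2.27. Of 20 granule genes, 4 were higher and 8 lower (-0.66, 0.41), and of 25 circulating neutrophil genes, 4 and 5 (-0.11, 58.54), with Retnlg at -2.91 and Mmp8 at -2.57. The highest ratios were those of Car4, a carbonic anhydrase absent in medium and 2540-fold above a floor of 3 counts (157 CPM), Lipg at 9.58, Adora2b, an adenosine receptor, at 9.36, Cxcl3 at 8.78 and Nr4a3 at 8.38. The low ratios included those of Adcy2, 106-fold lower by the same floor, and Dnah6 at -6.60. The bounds of Car4 and Adcy2 are smaller if both mates of a pair were counted.

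Arg1, Spp1, Vegfa and some fatty acid genes, 10 of 32, were at least 2-fold higher with linoleic acid beside GM-CSF than with GM-CSF. Arg1 (chromosome 10, 24915221-24927484) was at 42 CPM against 3.04 CPM with GM-CSF, log2 3.77 (3.43 to 4.16). Plin2 (chromosome 4, 86648386-86670060) was at 609 against 88.3 CPM, log2 2.79 (2.72 to 2.86), Cd36, the fatty acid translocase, at 181 against 21.1 CPM, log2 3.10 (2.96 to 3.24), and Fabp4 at 7.86 against 0.627 CPM, log2 3.56 (2.87 to 4.55). Vegfa was at 143 against 53.4 CPM, log2 1.42 (1.32 to 1.52), Spp1 at 1004 CPM, log2 1.58 (1.54 to 1.62), Cd274 at 629 CPM, log2 0.62 (0.581 to 0.658), and Myc at 16.5 CPM, log2 0.75 (0.515 to 1.01). Siglecf was at 62.4 CPM, log2 -0.33 (-0.437 to -0.231), Tnf at 834 against 813 CPM, Ly6g at 126 CPM, log2 1.17, and Ccl3 had 1.05. The GM-CSF and linoleic acid library came from an animal of the other sex, with Xist at 0. Against a floor of 3 counts Xist was 2800-fold lower, and Ddx3y, Eif2s3y, Kdm5d and Uty were 1770, 1730, 232 and 163-fold higher. These bounds are smaller if both mates of a pair were counted. Every contrast with this library therefore joins treatment and animal. In all, 1231 genes were 2-fold higher and 164 lower of 11259, an 88.2% share that TMM scaling put at 80.5% and DESeq2 size factors at 75.6% (960 and 310), and without genes of the sex chromosomes the total of 1395 was 1347. The 32 fatty acid genes had 0 at 2-fold lower (median 0.377, percentile 99.88), while 24 cholesterol synthesis genes had -0.18 (1.17) with 15 negative values and 16 lipid desaturation genes 0.329 (88.82). Higher at 2-fold were, of 20 hypoxia genes, 10 (0.999, 100), with P4ha1, a collagen hydroxylase, at 1.78 and Pdk1 at 1.64, and of 37 MYC targets, 7 (0.64, 100), with Nop56 at 1.36. Of 30 cell cycle genes, 9 were higher (0.885, 100), of 10 eosinophil genes, 9 (1.68, 100), and of 16 macrophage genes, 7 (0.958, 99.99), with Mrc1 at 2.00. Of 25 SiglecFhi TAN markers, 8 were higher and 1 lower (0.266, 99.91). The 20 granule genes had -0.49 (percentile 0) and the 11 MHC class II genes -0.44 (0.11). Beyond the sex-linked genes the highest ratios included Epb41l3 at 3.57 and Slc16a9 at 3.49, and the lowest Fosb at -2.46 and Gstt1 at -1.91. Against medium, GM-CSF and linoleic acid together had 2969 genes 2-fold higher and 1519 lower of 11511, and the median of all genes was 0.197, or 0.0287 after TMM.

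Few genes differed with linoleic acid in the absence of GM-CSF, and Acot1, Cpt1a and Plin2, all of fatty acid handling, were among the higher ones. Acot1, an acyl-CoA thioesterase (chromosome 12, 84009490-84018371), was at 81 against 18.9 CPM, log2 2.10 (1.95 to 2.26), Cpt1a, the gate of mitochondrial fat oxidation (chromosome 19, 3322334-3385733), at 158 against 72.8 CPM, log2 1.12 (1.04 to 1.21), Plin2 at 237 against 113 CPM, log2 1.06 (0.995 to 1.13), and Klf11 (chromosome 12, 24651274-24662789) at 11.6 against 4.22 CPM, log2 1.45 (1.12 to 1.82). Siglecf had -0.32, Myc -0.81 and Cd274 0.15. In all, 88 genes were 2-fold higher and 292 lower of 10696. Of 30 fatty acid genes, 4 were higher and 1 lower (median -0.00601, percentile 61.52). Of 9 platelet genes, 3 were higher (0.691, 100), with Ppbp at 1.85 and Pf4 at 1.43, and of 10 erythroid genes, 7 were lower (-1.07, 0). Erythrocyte genes also had the lowest ratios, Dmtn -3.15, Trim58 -2.87, Ermap -2.78 and Slc6a9 -2.76. Of 36 MYC targets, 0 were higher and 3 lower (-0.38, 0.01). Both times linoleic acid was added, 22 genes were 2-fold higher, where independent lists would share 4.85, and these included Acot1, Cpt1a, Klf11, Plin2, Hilpda, Pf4 and Ppbp.

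With the MYC-MAX inhibitor added to GM-CSF and linoleic acid, Cxcl2, Spp1, Arg1 and Ccl3 were lower, and Acot1 was higher. Cxcl2 was at 41.3 against 5931 CPM, log2 -7.17 (-7.25 to -7.08), Spp1 at 22.6 against 1004 CPM, log2 -5.47 (-5.59 to -5.35), Arg1 at 1.19 against 42 CPM, log2 -5.10 (-5.71 to -4.63), and Ccl3 at 98.2 against 1869 CPM, log2 -4.25 (-4.31 to -4.19). Cd274 was at 114 against 629 CPM, log2 -2.46 (-2.52 to -2.4), Vegfa at 32.4 against 143 CPM, log2 -2.14 (-2.25 to -2.03), Myc at 6.75 against 16.5 CPM, log2 -1.29 (-1.56 to -1.03), and Siglecf at 50.1 against 62.4 CPM, log2 -0.31 (-0.425 to -0.205). Tnf had -2.33 and Hif1a -0.97, while Cxcr2 had 0.87 and Xbp1 0.41. In all, 1349 genes were 2-fold higher and 1669 lower of 11477, a 44.7% share that TMM scaling put at 38.2%. Of 31 NF-kB genes, 26 were 2-fold lower and 0 higher (median -2.67, percentile 0), of 25 SiglecFhi TAN markers, 16 lower and 1 higher (-2.06, 0), of 20 hypoxia genes, 11 and 1 (-1.32, 0), of 20 immunosuppressive mediators, 10 and 0 (-1.26, 0), and of 37 MYC targets, 15 and 0 (-0.91, 0), with Gnl3 at -2.55. Of 19 glycolysis genes, 9 were lower and 1 higher (-0.66, 0.045), with Pfkl at -2.65. The 32 fatty acid genes had 7 lower and 5 higher members (0.15, 36.78). Acot1 was at 110 against 8.16 CPM, log2 3.75 (3.53 to 3.98), and Plin2 at 346 against 609 CPM, log2 -0.82, but 1.969 against the GM-CSF library. Of 20 granule genes, 5 were higher and 4 lower (0.692, 99.77). Other low ratios were those of Nr4a3 at -6.31, Ciart, a clock gene, at -5.92, Csf1 at -5.90 and Ptgs2 at -5.74, and the highest included H2bc8 at 4.54 and Slc25a27 at 4.06. The reference library is the one from the other sex. Against the GM-CSF library the medians were -1.07 for SiglecFhi TAN markers, -2.07 for NF-kB genes, -0.48 for hypoxia genes, -0.15 for MYC targets and 0.635 for fatty acid genes, and 1508 genes were 2-fold apart (899 higher and 609 lower). There Cxcl2 had -5.917, Spp1 -3.886, Ccl3 -3.198, Arg1 -1.331, Cd274 -1.84, Vegfa -0.7206, Siglecf -0.65 and Myc -0.53.

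**Figure D4:**
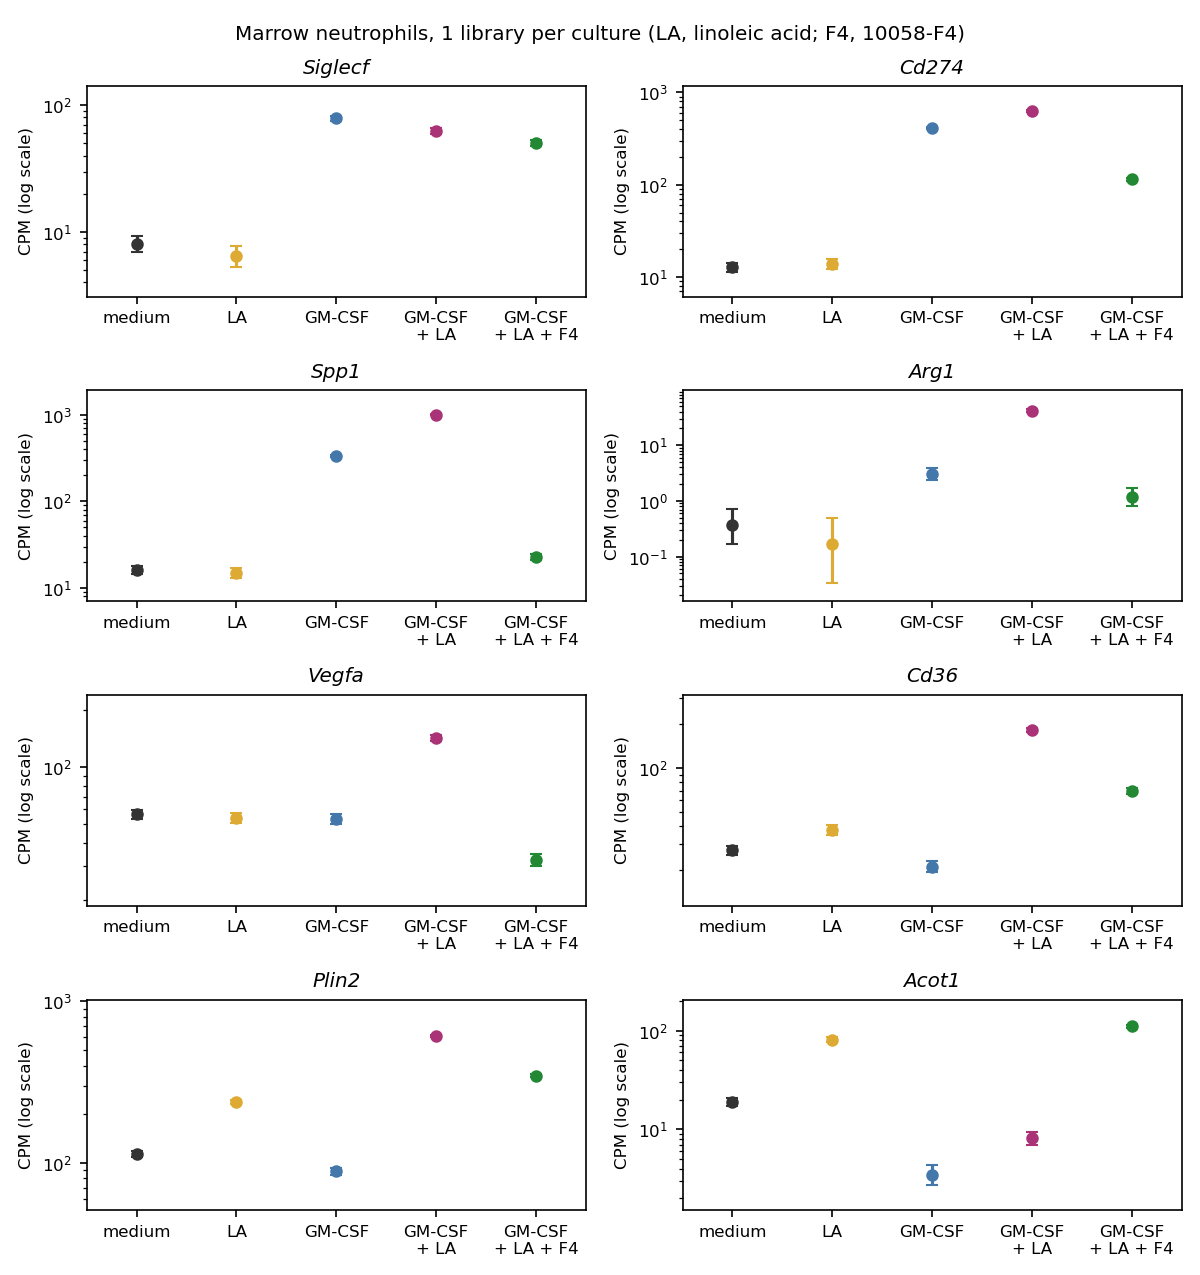
CPM (log axis) of named genes in the 5 marrow neutrophil libraries, 1 per condition, with exact Poisson 95% intervals. Cd274 is at 12.7 CPM in medium, 409 with GM-CSF, 629 with GM-CSF and linoleic acid and 114 with the MYC-MAX inhibitor, and Plin2 is at 113, 88.3, 609 and 346.

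Genes that differed between purified TANs were followed in the marrow libraries. Since no gene passed the test, the 200 genes with the lowest unadjusted p among those at least 2-fold apart were taken in each direction, a choice made after seeing the data. With GM-CSF against medium, 188 measured genes of the SiglecFhi side had a median of 0.515 (percentile 100) and 197 of the SiglecF- side -0.62 (0). Linoleic acid beside GM-CSF gave 0.15 (95.3) and -0.05 (27.3), and linoleic acid without it -0.12 (0.03) and 0.022 (99.5). With the MYC-MAX inhibitor the medians were 0.138 (18.3) and 0.305 (96.4), and the first turned to -0.0806 (0.01) for genes ranked with the replicate block, a choice also made after seeing the data.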

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

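The tests of explanations in this part and the count of other splits were written down after the result was seen, while the calls by edgeR, DESeq2, camera and fry were planned.

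Counts of Y-linked genes, which no comparison used, were 0 in both libraries of RIL-175 alone and came to 67 over the 6 coculture libraries: 4, 8 and 11 with SiglecF- TANs and 14, 12 and 18 with SiglecFhi TANs. Each coculture library had some, so RNA of cells from a male animal, with leukocytes a candidate source, may be part of the leukocyte signal. The purified TAN libraries, the reference for the share, held no Y-linked gene among the genes deposited. Genes with low counts had been removed from them, and their Xist was at 46.4 to 434 CPM. They therefore show no sign of male cells, and whether the cocultured TANs came from other animals was not tested. Against TAN RNA with the purified profile at 1 share as the whole cause, the 90th percentile of the share per gene was at least 16.3 times the 10th in each library (up to 56.7), and with SiglecFhi TANs the abundant S100a9 stood at 0.0246% of its purified level and Saa3 at 20.9%. For the NF-kB list, 10 of 11 members that are not TAN-expressed were called higher with SiglecFhi TANs. The 9 of these with a purified level rose at least 26 times as much as the largest 90th percentile share allows (median 126). Sod2, which was not called, rose 3.29 times as much. Members chosen for low purified levels and for being called must largely exceed that share, so such multiples were nearly fixed in advance. They say only that RNA carried at that share falls short of these 9 rises. Genes called lower with SiglecFhi TANs fell by a median of 14.8%, against a largest 90th percentile share of 0.418%. A fall as small as that share could hardly be called, so this gap was also nearly fixed in advance. It says only that dilution at that share falls short of the falls called. A TAN profile changed by coculture, other leukocytes that a further sort of the RIL-175 cells would remove, and a response of RIL-175 stay open.

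For the 252 genes called between the cocultures, the 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of 10, gave 252 genes and the highest of the others 0.

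In the marrow, lists were compared for linoleic acid beside GM-CSF and without it, 32 in all. In 4 lists the median log2 ratios had opposite signs and lay outside the middle 95% of random lists both times: MYC targets (0.64 beside GM-CSF and -0.384 without), glycolysis (0.28 and -0.112), macrophage genes (0.958 and -0.384) and unfolded protein response genes (0.358 and -0.196). The differences were 1.02, 0.392, 1.34 and 0.554. The values beside GM-CSF rest on the library from an animal of the other sex, so these differences join treatment and animal. With 1 library per condition the difference was not tested.

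The library with GM-CSF and linoleic acid came from an animal of the other sex, and 1187 autosomal genes were 2-fold higher in it than in the GM-CSF library (median 1.38). In the library with the inhibitor, which also held linoleic acid, their median over the GM-CSF library was 0.257, beside 0.249 for all 10927 genes, and 14.3% of them were 2-fold higher against 7.06% of all. Another animal or preparation, linoleic acid and a reversal by the inhibitor cannot be told apart for these genes, because each condition has 1 library. The 10 fatty acid genes among them kept a median of 1.25 (2.09 beside GM-CSF), above the 95% range of random sets of the genes 2-fold higher (-0.251 to 0.741). The inhibitor library differed from the GM-CSF library by the inhibitor as well as by linoleic acid. The median would argue against another animal as that list's whole cause only if the inhibitor did not raise these genes, which was not tested. Among members also 2-fold higher without GM-CSF, Acot1 and Cpt1a had 4.96 and 2.56 over the GM-CSF library with the inhibitor. Without it they had 1.21 and 1.25. Plin2 and Hilpda went the other way, at 1.97 and -0.0142 against 2.79 each. The condition is in doubt for some members, so the median cannot decide. For the list an effect of linoleic acid is a hypothesis found and tested on the same data. The sex of the animal stays open for the list and for the rest.

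Circulating neutrophil genes were lower in SiglecFhi than in SiglecF- TANs, though edgeR called 0 genes (2712 at an unadjusted p under 0.05, and 1219 by DESeq2), and the call of the list was lost with an estimated correlation (adjusted p 0.522) and with fry, which called 0 lists. Within the replicate numbers the medians were -3.42 and -2.75, so neither number alone carried the fall. Each population held a library of each number, so structure shared by the numbers could not produce this difference. The medians therefore do not test that explanation. The median of the circulating neutrophil list minus that of the pan-leukocyte list was -1.98 in the number with the smaller gap. That argues against a lower share of leukocytes as the whole cause. The pan-leukocyte list was itself lower, with a median of -1.02, so such a share stays open as a part of the fall. Whether SiglecFhi TANs differ in maturity, in other granulocytes or in handling after the sort stays open and was not tested.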

How the results depend on the processing

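Of the alternatives below, library-total scaling, the restriction to genes of RIL-175 alone, the ranking with the replicate block, the removal of sex chromosome genes and the comparison with the GM-CSF library were added after seeing the data.

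Between purified TANs edgeR called 0 genes, also with DESeq2 size factors, a 1 CPM filter, library totals and the 1.5-fold test. The alternative without a filter removed no gene and says nothing. DESeq2 called 1219 and the replicate block 3278. The count was 0 to 113 with each library left out, 4 without SiglecFhi replicate 1 and 113 without SiglecFhi replicate 2. With 1 library left in a population, that library is assumed to vary like the 2 of the other. The deviations of libraries with the same number correlate at 0.61. That is a single value, because with 2 libraries per population the deviations from the mean are mirror images. Of 13 lists, 0 were called with an estimated correlation and 0 by fry, and 12 to 20 with each library left out (20 without SiglecFhi replicate 2). The cause was not tested.

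For RIL-175 with SiglecF- TANs the 439 calls became 130 in the 1.5-fold test, 177 without TAN-expressed genes and 209 among genes of RIL-175 alone, the last 2 from fewer genes tested. They were 283 to 626 with each library left out (a lone library of RIL-175 alone is assumed to vary like the other groups), 283 without SiglecF- replicate 1. With SiglecFhi TANs the 1102 calls became 189 in the 1.5-fold test, 722 without TAN-expressed genes and 740 to 1292 with each library left out. Between the cocultures the 252 calls became 22 in the 1.5-fold test and 405 with only the groups compared, and 131 to 439 with each library left out: 439 and 434 without RIL-175 alone replicate 1 or 2, 164 and 135 without SiglecF- replicate 1 or 2, and 145 and 131 without SiglecFhi replicate 2 or 3. A stricter null explains the 1.5-fold counts, and the cause of the others was not tested. Both comparisons with the control shared 121 genes without TAN-expressed genes. DESeq2 size factors, DESeq2, library totals, both filters and the replicate block stayed within 1.5 times in all 3 comparisons.

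The lists called fell from 10 to 5 (SiglecF- TANs), from 13 to 4 (SiglecFhi TANs) and from 8 to 0 (between cocultures) with an estimated correlation. In the same order fry gave 12, 14 and 2. Without TAN-expressed genes they were 3, 2 and 4, and among genes of RIL-175 alone 3, 4 and 2, with fewer members tested. Between the cocultures they were 5 to 9 with each library left out, 5 without SiglecF- replicate 1. Without TAN-expressed genes 3 lists that had been called changed direction, in 5 results. These were the SiglecFhi TAN markers (camera adjusted p 0.286 with SiglecF- and 0.828 with SiglecFhi TANs), the GM-CSF and STAT5 genes (0.583 and 0.383) and the immunosuppressive mediators with SiglecFhi TANs (0.383). Lists called in neither fit, such as glycolysis with SiglecF- TANs, also changed direction and are not counted here.

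In the marrow, at 20 counts the 380 genes apart with linoleic acid became 819, as more low genes enter. The totals of the other pairs stayed within 1.5 times, except the inhibitor against the GM-CSF library, with 1508 for 3018. By direction, the 164 genes lower with linoleic acid beside GM-CSF were 255 with TMM, 310 with DESeq2 size factors and 267 at 20 counts. Against the GM-CSF library 11 genes named for this pair at 2-fold or more changed sign: Xist -0.4751, Tsix -0.9231, Cd36 1.711, Wfdc17 0.2267, Me1 0.8457, Pmepa1 0.1203, Mmp13 0.9613, Afp 1.255, Ear1 0.2303, S100a10 0.1253 and Pecam1 0.03955. So did, from under 2-fold, Plin2 1.969, Fabp5 0.7907, Ly6g 0.5769, Nkg7 0.6168, Trf and Slc4a1. Epx 0.1076, Prg2 0.4516 and Mrc1 0.6878, named for other pairs, changed sign too. Of 1187 autosomal genes 2-fold higher with linoleic acid beside GM-CSF, 1136 were negative for the inhibitor against that library, with a median of 0.257 against GM-CSF. The NRF2 (0.137), eosinophil (0.26), cell cycle (0.363), mast cell (0.271) and pan-leukocyte (-0.113) lists changed sign too, and the dendritic list had -0.0577 with GM-CSF at 20 counts. Of the TAN gene sets, 50 genes gave 0.0564 with linoleic acid, -0.765 with GM-CSF and -0.298 with both against medium for the lower set, 0.036 (higher) and 0.0705 (lower) for linoleic acid beside GM-CSF and 0.29 (higher) with the inhibitor. The block ranking gave -0.796 (lower, both against medium), 0.232 (higher, beside GM-CSF) and -0.0806 (higher, inhibitor), and TMM -0.699 (lower, both against medium), 0.0432 and -0.16 (higher and lower, beside GM-CSF). The cause was not tested.

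The values compared under the alternatives were those of named genes and, for the cocultures and TANs, also the counts of genes called higher and lower. Of these, 3972 of 4476 in the cocultures, 3285 of 3769 in the marrow and 207 of 231 in TANs held. In TANs and cocultures a value held if it kept its side of the threshold. A change of direction counted against it only where a fit called it. TAN genes that changed sign without a call, such as Arg1 and Xbp1, therefore count as held. A marrow value held if it stayed within its spread, and a count if it stayed within 1.5 times. Of the values of lists, 902 of 981, 753 of 777 and 195 of 245 held. The share of TAN RNA from 200 genes was 0.066% and 0.0927%, within 1 SD. Depth limits genes at 0: the floor over a group was 0.0581 CPM in RIL-175 alone.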

Other observations

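In purified TANs Xist was at 46.4 and 191 CPM in the SiglecF- libraries and at 428 and 434 CPM in the SiglecFhi libraries. In the cocultures Xist had 1 count in SiglecF- replicate 3, 2 counts in SiglecFhi replicate 3 and 0 in the others.

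In the marrow libraries the eosinophil granule genes Epx and Prg2 were at 2.73 and 14.4 CPM in medium, 0.22 and 8.39 with linoleic acid, 7.7 and 12.2 with GM-CSF, 18 and 40.7 with GM-CSF and linoleic acid and 8.3 and 16.6 with the inhibitor. With GM-CSF against medium, 13 of 22 unfolded protein response genes were 2-fold higher and 0 lower (median 1.36, percentile 100), and of 30 interferon genes 14 were higher and 4 lower (0.656, 99.94). With the inhibitor, against GM-CSF and linoleic acid, 11 of 21 TGF-beta response genes were 2-fold lower and 3 higher (-1.19), and of 16 macrophage genes 10 were lower and 0 higher (-1.71). That reference is the library from the other sex, and against the GM-CSF library the medians were -0.14 and -0.44. Of the 22 genes 2-fold higher both times linoleic acid was added, 8 were also 2-fold higher in the inhibitor library than in the GM-CSF library.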
